A study of Mus musculus with 6 samples.

How the data were processed

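RNA from 6 cultures of a murine myeloid leukemia line that carries the MLL/AF10(OM-LZ) fusion was hybridised to Affymetrix MTA-1_0 transcriptome arrays, 1 array per culture. A pair of lines carried KRAS, as the wild-type form or as KRAS-G12C, and another pair carried PTPN11, as the wild-type form or as PTPN11-G503A. The last pair was a negative control without Hoxa11 and a line with Hoxa11. Per the labels' protocols, the cells had no treatment and grew for 16 h in medium with 20% fetal serum and 10 ng/ml interleukin-3, and total RNA was taken with Trizol and labelled with biotin.

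The values are log2 signals per transcript cluster as the authors deposited them. Per the submitters' processing notes, RMA and the Transcriptome Analysis Console were used; their versions, the variant of RMA, any centring and the genome build are not given in the sources used here. The log2 scale was read from the deposited values, which ran from 2.27 to 19.2 with array medians between 3.77 and 3.82. No further normalization was applied. The difference between log2 values of a pair of arrays is called the log2 difference, and a fold is the corresponding ratio of signals. RMA compresses differences of dim clusters, so folds of genes near background are understated.

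Of 65956 clusters, 30638 had exactly 1 gene symbol in the platform annotation, 2176 had several and 33142 were not listed there. Only clusters with 1 symbol were named. Of those symbols, 22596 were matched by Entrez identifier to the RefSeq table of assembly GRCm38.p6, and 0 had to be updated. That table was used for gene classes and for which genes neighbour each other, and no coordinates are printed because the build of the array's annotation is not named. For the 354 genes with several clusters the one with the highest mean over the 6 arrays was kept. No such gene had clusters 2-fold apart in opposite directions in any comparison. This left 30176 genes. Kras had no cluster with a single symbol and was not analysed here.

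The number of arrays limits the precision. Each group holds 1 array, so no single comparison has a test, an error or a p-value, and "higher" and "lower" describe these arrays. A gene counted as apart when its log2 difference was at least 1 (2-fold) in either direction and its signal exceeded the median of all genes, log2 4.09, in at least 1 of the arrays compared. Each changed line was set against its own control, and the 3 control arrays were set against each other to show how far lines differ without the studied change. The comparisons share no array. Correlations of log2 differences are across genes, which are not independent replicates.

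The only test was limma 3.58.1 (R 4.3.3) on the 4 KRAS and PTPN11 arrays, with terms for the locus and for the mutated state. The disagreement between both mutations' effects was its error, with 1 residual degree of freedom per gene and 4.12 prior degrees of freedom from eBayes. It asks whether a change is common to both mutations. P-values were adjusted by Benjamini-Hochberg over 15950 genes, with a threshold of 0.05. On simulated data of that size it recovered 50.0% of 50 genes changed by log2 1 and 82.0% of those changed by 1.5. It recovered 100.0% of those changed by 2 or 3, with 15 false calls in all. The simulated noise was normal, independent between genes and drawn from the spread that limma itself had fitted. The simulated changes were also equal in both mutations and more numerous than the genes called in the data. For these reasons the shares do not carry over. In the data Ms4a4c, with a mean log2 difference of 1.04, had an adjusted p of 0.25. Prrg4, with 1.52, had one of 0.10.

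For 37 gene lists fixed before the data were examined, the median log2 difference of members above the filter was given as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Lists with fewer than 5 such members got no percentile. A median below the 2.5 or above the 97.5 percentile is called outside the central 95%, which describes these arrays and is no test, since members of a list vary together. On simulated lists of 15 genes among 15000, a shift of 0.5 put 20 of 20 lists outside, a shift of 0.15 put 8 of 20 and no shift put 1 of 20 outside. Small shifts can therefore be missed.

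Genes were named by a rule fixed before the data were examined. It takes the studied genes, the 10 largest differences of each direction per comparison, and the 10 genes of each direction with the largest smaller difference in both mutant comparisons. It also takes the genes moved the same way in all 3 comparisons, up to 4 members of each list with the largest difference, and 5 genes of each direction with opposite differences in the mutants. Predicted genes, small RNAs, receptor segments and pseudogenes were left out of the rankings. Genes named outside this rule are marked as such.

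Alternatives were median centring, quantile normalization, loess of the difference on the mean, no filter, a filter at the 75th percentile, the mean of all clusters of a gene, the mean of the 3 control arrays as control, thresholds of 1.5-fold and 3-fold, Spearman's rho, and limma with a trend, with a robust trend or without the locus term. Alternatives chosen after seeing the data were protein-coding genes only and a difference of 2-fold beyond all 3 control arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest.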

Results

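Expression was profiled in 6 cultures of mouse myeloid leukemia cells driven by the fusion of MLL with AF10, a chromatin-associated partner. The arrays formed 3 pairs, each with its own control. KRAS-G12C, an activating change of the small GTPase KRAS, was set against wild-type KRAS. PTPN11-G503A, a change in the phosphatase SHP2, was set against wild-type PTPN11. Cells with Hoxa11, a homeobox transcription factor, were set against cells without it. Each group held 1 array, so no difference in a single comparison has a replicate check. Array medians over all clusters lay between 3.77 and 3.82 on the log2 scale.

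The signal of the studied genes was examined in all arrays. The Hoxa11 cluster was dim throughout: its log2 signal was 3.78 without and 4.37 with Hoxa11, a log2 difference of 0.58 that exceeded those of 99.3% of 6678 genes of like brightness. Hoxa11 was higher in KRAS-G12C, at 5.59 against 3.71 with wild-type KRAS. In PTPN11-G503A it was 4.44, against 3.83 with wild-type PTPN11. The rises in the KRAS and PTPN11 pairs exceeded those of 99.9% and 98.4% of genes of like brightness. Whether the array's Hoxa11 probes cover an introduced copy is not given in the sources used here. Ptpn11 was bright and nearly level, with log2 differences of -0.10, 0.13 and 0.04 in the KRAS, PTPN11 and Hoxa11 comparisons. Its log2 signal was lowest in both PTPN11 lines, at 11.29 and 11.42 against 11.48 to 11.68 in the others, and whether its probes cover an introduced copy is not given either. Kras was not analysed here.

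At the 2-fold threshold the control lines differed from each other by more genes than any changed line differed from its control. Between wild-type KRAS and wild-type PTPN11, 712 genes were at least 2-fold apart, of which 295 coded for protein and 275 were small RNAs. Wild-type KRAS and the line without Hoxa11 were apart in 511 genes, and wild-type PTPN11 and the line without Hoxa11 in 539. Within the pairs the numbers were 212 for KRAS, 439 for PTPN11 and 222 for Hoxa11. At a 1.5-fold threshold this still held for the KRAS pair, with 597 genes, and the Hoxa11 pair, with 751. The control pairs then had 2049, 1527 and 1695 genes. The PTPN11 pair, with 1866, lay below only the largest of them. Among protein-coding genes at 2-fold, the numbers were 194 for KRAS, 289 for PTPN11 and 184 for Hoxa11. The control pairs had 295, 336 and 369 in the order above, so the PTPN11 pair lay only just below the lowest.

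**Figure D1:**
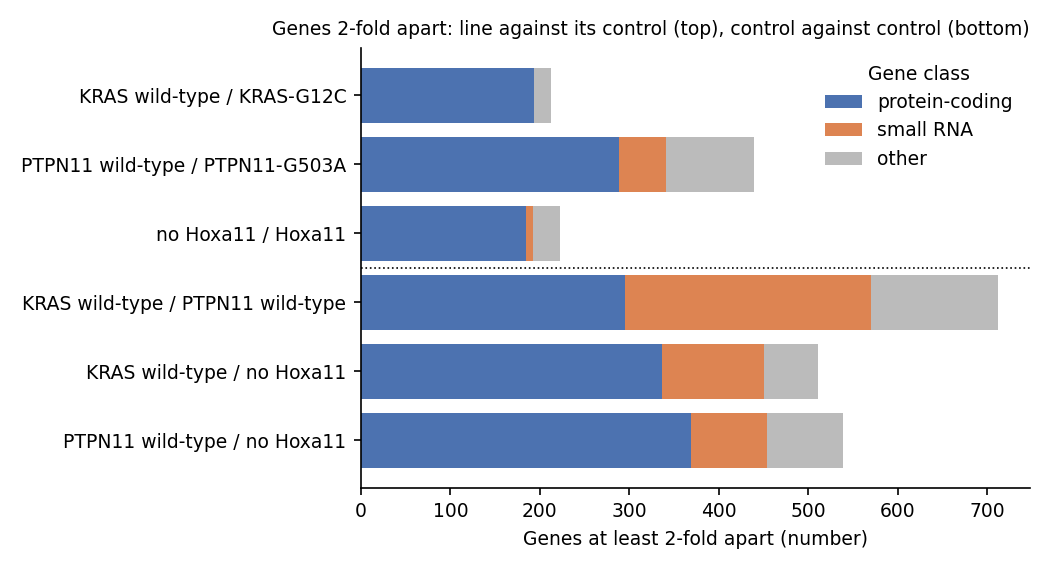
Number of genes at least 2-fold apart between 2 arrays (x axis) for each changed line and its control (top 3 bars) and for each pair of control lines (bottom 3 bars), split by gene class. The control pairs lie between 511 and 712 genes and the changed lines between 212 and 439.

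KRAS-G12C cells had higher signals than wild-type KRAS cells for the complement regulator Cd55 (20.9-fold), the creatine synthesis enzyme Gatm (16.3-fold) and the nuclear factor Tox, and for genes of the Hoxa cluster. They had lower signals for the steroidogenic enzyme Cyp11a1 (11.9-fold), the aldo-keto reductase Akr1c12 (log2 difference -3.46), the mast cell protease Cpa3 and the calprotectin subunit S100a8 (7.54-fold). Of 15336 genes tested for size, 111 were at least 2-fold higher and 101 lower. With the mean of the 3 control arrays as the control, 95 were higher and 169 lower. For 104 of the 212 genes (49.1%) the wild-type KRAS array lay farther from the 4 other arrays than KRAS-G12C did. Gatm was one with a low control: it was at log2 4.94 with wild-type KRAS, 8.96 in KRAS-G12C and 9.99 without Hoxa11, and its difference from the mean of the 3 controls was 1.59.

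The largest difference was that of the neurofilament gene Nefh, 53.6-fold higher in KRAS-G12C. Its log2 signal was 5.46 with wild-type KRAS and between 10.25 and 11.20 in the other arrays, so the wild-type KRAS array stood apart. Bhlhb9 and Gtf2ird1 had the same layout, with log2 differences of 3.13 and 3.30. For Ranbp17, with a difference of 3.89, wild-type KRAS was lowest at 4.13 and KRAS-G12C highest at 8.01, with the others between. Cd55, Zfp760 and Tmem178 were instead low in all 3 controls. Their log2 differences were 4.38, 3.59 and 3.48. Klhl22 was higher by 2.92. Among the lower genes, the fatty acyl-CoA reductase gene Far2 differed by -3.97, Clec11a by -3.24, Tctex1d1 by -3.20, the transcription factor gene Ikzf2 by -3.04 and Akr1c13 by -2.90. Perp was at 5.63 against 8.64.

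Of 11 Hoxa cluster genes listed, 8 had a cluster with a single symbol. Hoxa7 and Hoxa9 had several symbols on theirs and were not analysed. All 7 members of the Hoxa cluster above the filter were higher in KRAS-G12C, and 3 were at least 2-fold higher. These were Hoxa11, with a log2 difference of 1.87, Hoxa6 with 1.37 and Hoxa5 with 1.29, while Hoxa3 was at 0.91. Wild-type KRAS was the lowest control for these genes, and from the mean of the 3 controls Hoxa6 differed by 1.02 and Hoxa5 by 0.83, under 2-fold. The median of 0.91 lay at the 100.0 percentile of random lists. Other targets of MLL fusions had a median of 0.37, and 8 of 10 were above 0, among them Flt3 at 1.09, Bcl2 at 0.62 and Eya1 at 0.55. Wild-type KRAS was the lowest control for all 3 genes. Another control was at least as high as KRAS-G12C, and Flt3 differed by 0.35 from the mean of the 3 controls. Both list medians stayed outside the central 95% with that control. The same lists had medians of -0.05 and -0.05 in the PTPN11 comparison and 0.08 and -0.01 in the Hoxa11 comparison, all inside the central 95%.

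Several lists of mature myeloid genes had medians below 0 in KRAS-G12C against wild-type KRAS. Neutrophil granule and maturation genes had a median of -0.18, with 6 of 17 members at least 2-fold lower and 1 higher: S100a8 was at -2.91, S100a9 at -2.23, the ficolin gene Fcnb at -1.49 and Ly6g at 1.31, of which S100a8, S100a9 and Ly6g were under 2-fold against the mean of the 3 controls. For S100a8 and S100a9 it was the wild-type KRAS array that stood apart, at log2 8.79 and 6.70 against at most 7.33 and 4.82 in the others. Monocyte and macrophage markers had a median of -0.22, with Lyz2, which encodes lysozyme, at -0.73. With the mean of the 3 control arrays as the control, that median was 0.05. Mast cell and basophil markers had a median of -0.32, led by Cpa3 at -3.40, and lysosome genes one of -0.19. Cpa3 was high only with wild-type KRAS and without Hoxa11, at log2 6.86 and 5.90, and its 3.89 with wild-type PTPN11 was near the 3.46 of KRAS-G12C. Clec11a had the same layout, at 7.52 and 9.10 against 4.19 and 4.29. Eosinophil markers, with 3 members above the filter, had a median of -0.78. Inflammatory cytokines and NF-kB targets (-0.22), chemokine and adhesion receptors (-0.13), interferon-stimulated genes (-0.18), the unfolded protein response (-0.17) and G2 and M phase genes (-0.07) also had medians below the central 95% of random lists. So did cholesterol synthesis genes at -0.24, whose median was 0.01 against the mean of the 3 controls.

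In all, 12 of 31 lists with a percentile lay outside the central 95% in the KRAS comparison. By chance 1.55 would if list members varied like random genes, but they vary together, so more can. Against the mean of the 3 controls the medians of interferon-stimulated, NF-kB, unfolded protein response, G2 and M phase, lysosome, monocyte and cholesterol synthesis genes were inside it. So were G2 and M phase genes after quantile normalization and interferon-stimulated genes without the filter. Of the 212 genes, 49 were 2-fold beyond all 3 control arrays, 24 higher and 25 lower.

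PTPN11-G503A cells had far higher signals for the stefin genes, which encode cysteine protease inhibitors of the cystatin A family, than wild-type PTPN11 cells or any other line. Cstdc4 was 216-fold and Stfa2l1 213-fold higher. The cells also had higher signals for chemokine genes and for Cd24a, and lower signals for the coagulation factor gene F13a1 (8.37-fold) and for Plet1 (10.9-fold). Plet1 was at log2 8.12 with wild-type PTPN11 and between 4.22 and 4.96 in all other arrays, so there the control stood apart, while F13a1 was lowest in PTPN11-G503A. Of 15679 genes, 281 were at least 2-fold higher and 158 lower. For 125 of these 439 genes (28.5%) the wild-type PTPN11 array lay farther from the 4 other arrays than PTPN11-G503A did.

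The stefin genes lie next to each other on chromosome 16. Log2 differences were 7.76 for Cstdc4, 7.73 for Stfa2l1, 6.62 for Stfa1, 6.49 for Csta2, 6.26 for Csta3, 6.01 for Cstdc6, 5.96 for Stfa2 and 5.03 for Stfa3. In the other 5 arrays these genes had log2 signals of at most 6.22. The genes are near-identical copies, so the probes of one may also bind transcripts of another and the values of single members are uncertain. The nearest other genes above the filter, named after their values were seen, ranged from -0.38 for Slc15a2 to 0.45 for Kpna1.

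**Figure D2:**
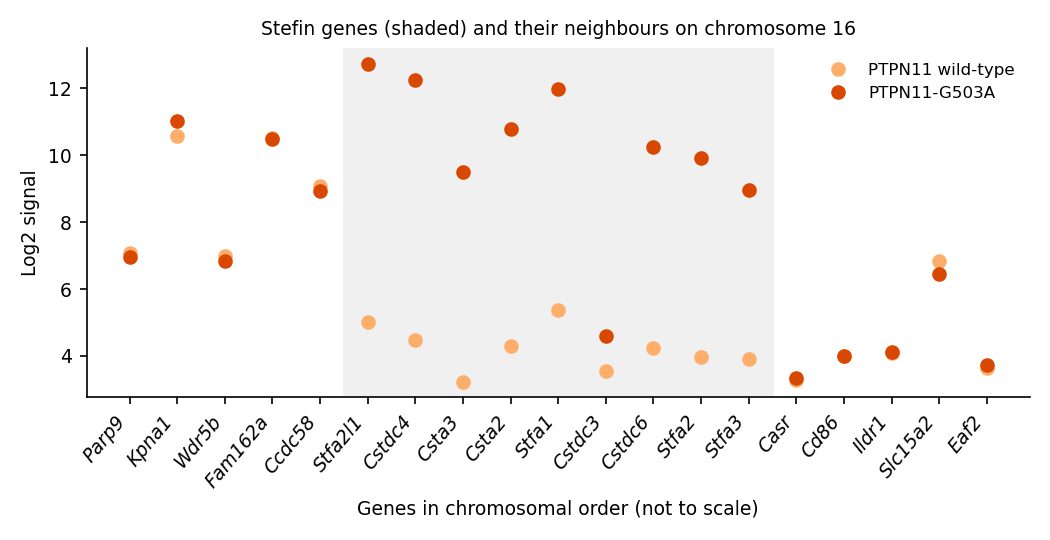
Log2 signal (y axis) of the stefin genes (shaded) and their neighbours in chromosomal order (x axis, not to scale) in the wild-type PTPN11 and PTPN11-G503A arrays, 1 point per array. Cstdc4 had a log2 signal of 12.25 with PTPN11-G503A and 4.49 with wild-type PTPN11, while the neighbour Fam162a had 10.48 and 10.52.

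Cd24a, a glycosylated surface protein gene, was 52.8-fold higher, and App, the amyloid precursor protein gene, 31.3-fold higher. Both were highest in the line without Hoxa11, at log2 14.32 and 12.75 against 13.36 and 12.22 in PTPN11-G503A. Wild-type PTPN11 was the lowest of all arrays for both, at 7.64 and 7.25. Lower genes included the complement receptor gene C3ar1 (-2.74), the potassium channel gene Kcnk5 (-2.63), Bahcc1 (-2.57) and Dock1 (-2.54). Cyp11a1, Tctex1d1, Ikzf2 and Akr1c12 were lower by log2 differences of -3.83, -3.82, -2.96 and -2.58.

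Inflammatory cytokines and NF-kB targets had a median of 0.54 in the PTPN11 comparison, at the 99.99 percentile, and 6 of 16 members were at least 2-fold higher. They included the chemokine genes Ccl9 at 4.55, Ccl3 at 2.73 and Ccl2 at 2.12 and the interleukin-1 receptor antagonist gene Il1rn at 3.07. Ccl9 was also bright in the line without Hoxa11, at log2 13.20 against 13.97 in PTPN11-G503A. Monocyte and macrophage markers had 4 of 17 members at least 2-fold higher, namely Lyz2 at 2.86, Msr1 at 2.03, Cd14 at 1.95 and Ccr2 at 1.91, but their median of 0.15 was inside the central 95%. The chemokine receptor gene Ccr1 was at 2.03. P53 targets had a median of 0.27, with Fas at 1.17 and Perp at -2.54. The phosphatase gene Dusp6, which is induced by ERK signalling, was at 1.93, and ERK pathway output genes as a list had a median of 0.18, inside the central 95%.

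Medians were below the central 95% for MHC class II genes (-0.73, H2-Ab1 at -1.19), stem and progenitor markers (-0.25, Gata2 at -1.19 and Cd34 at -1.11), neutrophil granule and maturation genes (-0.24), RAS pathway genes (-0.17, Gab2 at -0.93), glycolysis and hypoxia genes (-0.24, Slc2a3 at -1.21) and immediate early genes (-0.20, Zfp36 at -0.85). Against the mean of the 3 controls the glycolysis and hypoxia median was 0.07 and, like that of p53 targets, inside the central 95%. The immediate early median became 0.42, at the 99.99 percentile, so it passed from below the central 95% to above it. Immediate early genes were inside it without the filter. H2-Ab1 was at log2 7.12 with wild-type PTPN11, 5.92 with PTPN11-G503A and at most 6.33 elsewhere. With the 3 controls averaged, H2-Ab1 (-0.51) and Slc2a3 (-0.23) were under 2-fold, H2-Oa turned from -0.86 to 0.41, and the MHC class II median stayed below the central 95%.

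In all, 8 of 31 lists lay outside the central 95%. Small RNAs moved with this pair. Of 1162 small RNA genes, 51 were at least 2-fold higher in PTPN11-G503A and 1 lower, with a median log2 difference of 0.29. Among protein-coding genes 147 were higher and 142 lower, so the excess of higher genes lay outside them. After centring each array on its median, 223 genes were higher and 199 lower. Against the mean of the 3 control arrays 550 were higher and 136 lower, and 157 higher and 36 lower genes were 2-fold beyond all 3 controls.

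The KRAS and PTPN11 comparisons address whether both mutations, which act in the same signalling pathway, went with common changes. Cd55 was higher in both mutants by nearly the same amount, 20.9-fold and 21.4-fold, and Cyp11a1 was lower by 11.9-fold and 14.2-fold. In all, 28 genes were at least 2-fold higher in both and 23 lower in both, against 1.96 and 1.00 for independent lists. Another 17 were apart in opposite directions, against 2.88 for independent lists. Across 15950 genes the log2 differences had a Pearson's r of 0.22 and a Spearman's rho of 0.18.

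Under limma's additive fit, 12 genes changed in common at an adjusted p of 0.05 or less. The complement regulators Cd55 (mean log2 difference 4.40, SE 0.14, adjusted p = 0.0069) and Cd59a (2.18, SE 0.15, adjusted p = 0.039), Tmem178 (3.46), Zfp760 (3.22) and the lymphocyte surface receptor gene Ly9 (2.18) rose. Cyp11a1 (-3.70, SE 0.15, adjusted p = 0.0083), Tctex1d1 (-3.51), Ikzf2, Perp (-2.77), Akr1c13 (-2.69), C3ar1 (-2.57) and the desmosome gene Dsp (-2.28) fell. Each of these genes moved the same way in both pairs. The count was 1 after quantile normalization and 0 without the filter, where the smallest adjusted p was 0.0506. With protein-coding genes only it was 4, although all 12 genes code for protein.

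Not all of these levels were particular to the mutants. Tctex1d1 was as dim in the line without Hoxa11 (3.92) as in KRAS-G12C (4.20) and PTPN11-G503A (4.02), and Cd59a was as bright there (7.64) as in the mutants (7.21 and 7.02). Cd55 was between 5.26 and 6.24 in the 4 arrays without a mutation. Other genes moved in both pairs without passing the test were Akr1c12 (-3.46 and -2.58), Far2 (-3.97 and -1.92), the sorting receptor gene Sorl1 (-1.69 and -2.06), the kinase gene Bmx (1.62 and 1.82), Irx5 (1.46 and 2.31), Prrg4 (1.44 and 1.59), Tox (3.15 and 1.42) and Ccl9 (1.92 and 4.55). In the KRAS comparison Prrg4 (0.41) and Ccl9 (0.73) were under 2-fold against the mean of the 3 controls. Ccl9 was brighter in the line without Hoxa11 (13.20) than in KRAS-G12C (11.45). Far2 was dimmer in the line without Hoxa11 (6.42) than in KRAS-G12C (7.25) and PTPN11-G503A (7.24).

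**Figure D3:**
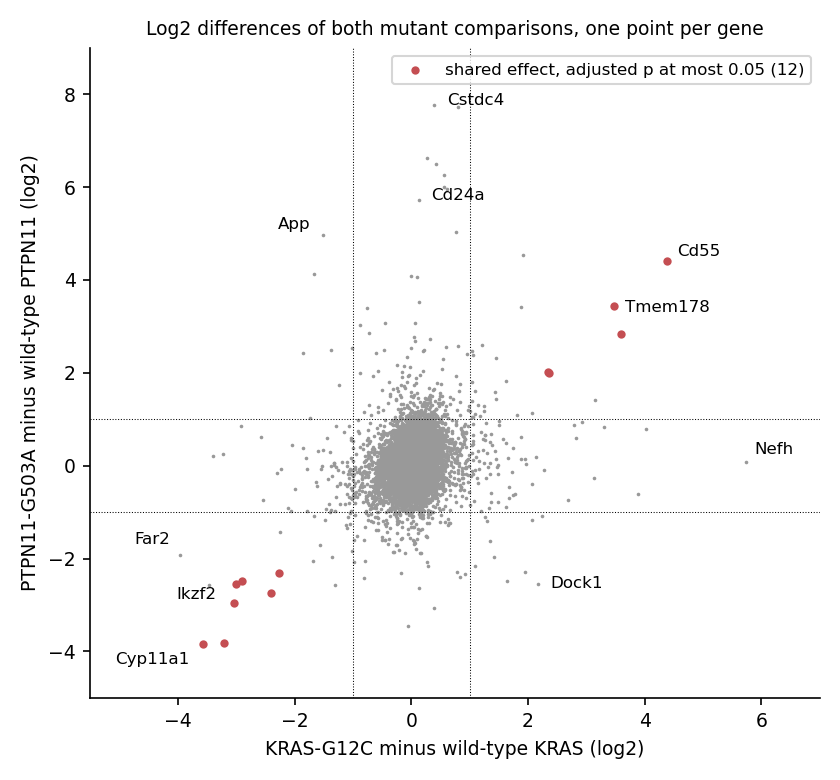
Log2 difference in the PTPN11 comparison (y axis) against that in the KRAS comparison (x axis), 1 point per gene, with dotted lines at 2-fold. The 12 genes with a shared effect are in red, Cd55 at the top right and Cyp11a1 at the bottom left.

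**Figure D4:**
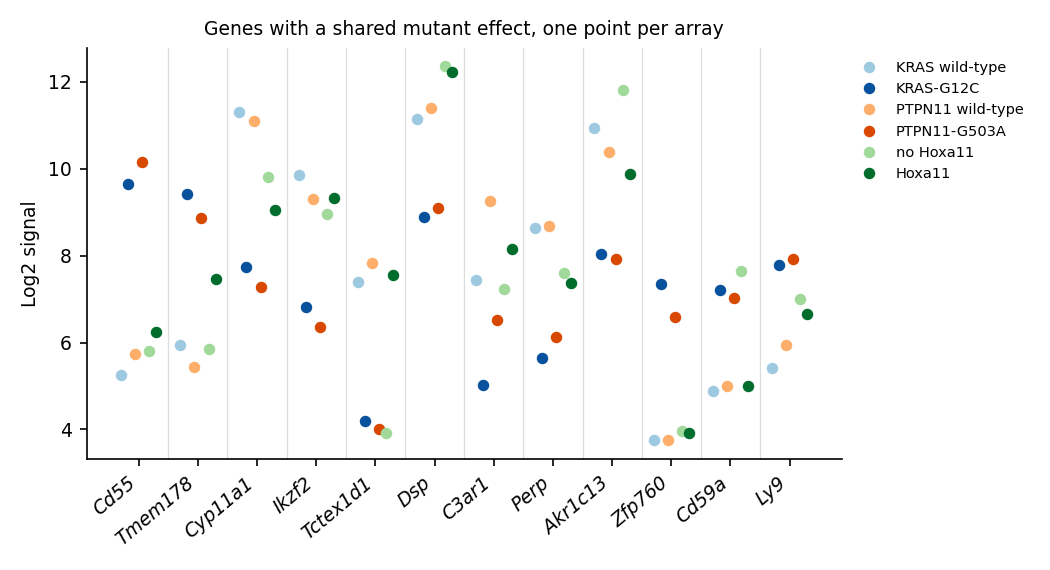
Log2 signal (y axis) of the 12 genes with a shared mutant effect in each of the 6 arrays, 1 point per array. Cd55 lies at 9.64 and 10.15 in the mutants and between 5.26 and 6.24 in the other arrays.

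Gene lists were also read on the mean of both mutant comparisons. ERK pathway output genes had a median of 0.13, at the 97.9 percentile. Dusp6 was at 0.76 in the KRAS and 1.93 in the PTPN11 comparison and the ETS factor gene Etv5 at 1.05 and 0.54. The Hoxa cluster (0.43) and p53 targets (0.18) were also above the central 95%. Fas was at 1.25 and 1.17. With the 3 controls averaged, Etv5 in KRAS-G12C (0.74) and Fas in PTPN11-G503A (0.60) were under 2-fold. Neutrophil genes (-0.24), MHC class II genes (-0.40), chemokine and adhesion receptors (-0.13), glycolysis and hypoxia (-0.14), cholesterol synthesis (-0.22), the unfolded protein response (-0.06), lysosome genes (-0.12) and RAS pathway genes (-0.10) were below it. Of all these lists, only the neutrophil genes lay outside the central 95% in both comparisons. The medians in the KRAS and PTPN11 comparisons were 0.91 and -0.05 for the Hoxa cluster, 0.03 and 0.27 for p53 targets, -0.19 and 0.06 for lysosome genes, 0.05 and -0.24 for glycolysis and hypoxia and -0.06 and -0.73 for MHC class II genes. The glycolysis median was 0.06 against the mean of the 3 controls, where chemokine and adhesion receptors, cholesterol synthesis, p53 targets and lysosome genes were inside the central 95%. ERK pathway output genes were inside it without the filter.

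In the limma fit, 1 of the 37 lists held a member that passed over all genes, namely Perp among the p53 targets. When adjusted over the list alone, 11 lists held 1 or more. There were 3 neutrophil genes (Cebpe, Csf3r and Fcnb), 2 ERK output genes (Dusp6 and Etv5), 2 p53 targets (Fas and Perp), 2 stem and progenitor markers (Cd34 and Gata2), 2 eosinophil markers (Epx and Siglecf) and 2 chemokine and adhesion receptors (Cxcr4 and Cd63). Flt3, Gata2, Ccl9 and Cd79b were the single members in the remaining lists, Flt3 in 2 of them. The B cell list had 1 member tested, so the value of Cd79b there is its unadjusted p of 0.0269. Cebpe, Csf3r and Cxcr4 are named here after their values were seen. The eosinophil list had 3 members tested, and Epx was near background, at log2 4.20 with wild-type KRAS and below the filter in the other KRAS and PTPN11 arrays. The other 26 lists held none adjusted over the list alone. No adjustment was made across the 37 lists, so some can hold such a member by chance.

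Cells with Hoxa11 had higher signals than their control for the histamine-degrading enzyme Hnmt (51.1-fold), the peroxidase Gpx3 (26.8-fold), Ly86 (24.0-fold), which encodes a partner of a Toll-like receptor homologue, and for monocyte genes. They had lower signals for the meiotic gene Hormad2 (47.4-fold), the growth factor gene Clec11a (32.8-fold) and Gatm (13.6-fold). Of 15418 genes, 100 were at least 2-fold higher and 122 lower.

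For most of these genes it was the control array that stood apart. It lay farther from the 4 KRAS and PTPN11 arrays than the Hoxa11 array did for 174 of the 222 genes (78.4%). Hnmt had a log2 signal of 5.27 without Hoxa11 and between 9.87 and 11.32 elsewhere. Hormad2 was at 9.44 without Hoxa11 and at most 4.13 elsewhere. Gpx3 was an exception, at 9.54 with Hoxa11 and at most 6.95 elsewhere. Of the 222 genes, 18 were 2-fold beyond all 3 controls, and 114 genes were apart from the mean of the 3 controls.

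Further higher genes were Tfpi (3.76), Sbf2 (3.68), Tctex1d1 (3.63), Dusp18 (3.40), the coagulation factor gene F7 (3.24), Cabcoco1 (2.66) and Sfmbt2 (2.64). Lower genes were the coagulation factor gene F5 (-4.99), the monoamine oxidase gene Maoa (-4.29), App (-3.47), the incretin receptor gene Glp1r (-3.39), the prostaglandin-degrading enzyme gene Hpgd (-3.33), Dnajc6 (-3.14) and Chst13 (-3.07). Against the mean of the 3 controls Hpgd was 1.79 higher in the Hoxa11 array.

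Monocyte and macrophage markers had a median of 0.38 in the Hoxa11 comparison, at the 100.0 percentile, and 7 of 17 were at least 2-fold higher, with Lyz2 5.67-fold and Ccr2 2.57-fold higher. The lysosome gene Psap was at 1.45, while lysosome genes as a list (0.10) were inside the central 95%. Mast cell and basophil markers (-0.65, Cpa3 at -2.24), dendritic cell markers (-0.42, Bst2 at -1.01 and Tcf4 at 1.51), MHC class II genes (-0.27), p53 targets (-0.20), stem and progenitor markers (-0.16), glycolysis and hypoxia (-0.15), cholesterol synthesis (-0.12) and S phase genes (-0.08) had medians below the central 95%. In all, 9 of 31 lists lay outside it. Inside it were monocyte markers and stem and progenitor markers against the mean of the 3 controls, cholesterol synthesis and S phase genes after quantile normalization, and mast cell, dendritic cell and stem and progenitor markers without the filter. Among JAK-STAT5 targets, whose median was -0.01, Il2ra was at -2.92. For Psap, Ccr2 and Tcf4 the control array was the lowest, at log2 12.79, 8.26 and 9.89. The other arrays were at 14.24, 9.11 and 11.17 or more. Bst2 was instead lowest in the Hoxa11 array.

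Across genes, the Hoxa11 differences had a Pearson's r of -0.02 with those of KRAS and 0.06 with those of PTPN11. Spearman's rho was -0.0008 and 0.18, the second of these as high as between both mutants. In the same direction 26 genes were apart in the KRAS and Hoxa11 comparisons and in opposite directions 36, against 1.488 and 1.502 for independent lists. For PTPN11 and Hoxa11 these numbers were 24 and 34, against 2.97 and 3.14. Moved the same way in all 3 comparisons were Tmem178 and Ms4a4c, which were higher, and Akr1c12, Akr1c13 and the thrombin receptor gene F2r, which were lower. Tmem178 was at 3.48, 3.43 and 1.60 and F2r at -1.66, -1.09 and -1.69.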

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

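All tests of explanations in this part were chosen after the results were seen.

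Some genes were at least 2-fold apart in opposite directions in the mutants, and the difference between the mutants was not tested. The KRAS-G12C effect minus the PTPN11-G503A effect was -6.48 (log2) for App, -5.79 for Mrgpra2a, -4.28 for Clec5a, -3.87 for Lilrb4a and -3.54 for Lilr4b. It was 4.72 for Dock1, 4.12 for C2cd4a, 3.37 for Map1b, 3.34 for Slco3a1 and 3.25 for Sbf2. Part of this rests on the wild-type KRAS array, the lowest control for Dock1 and Map1b. Against the mean of the 3 controls their KRAS-G12C differences changed sign, to -0.52 and -0.19. Those of Lilrb4a (0.28) and Lilr4b (0.19) changed sign too, but through the dim array without Hoxa11, at log2 8.54 and 5.13. For these genes KRAS-G12C, at 11.13 and 7.30, lay below both wild-type KRAS and wild-type PTPN11. Part rests on the wild-type PTPN11 array, where App was at log2 7.25 against at least 9.27 in all other arrays. Sbf2 was at 6.94 in PTPN11-G503A and 9.12 in its control, but 4.80 without Hoxa11. Slco3a1 was at 6.05 and 7.14, but 4.98 with wild-type KRAS. Mrgpra2a, Clec5a, Lilrb4a and Lilr4b were instead brightest in PTPN11-G503A. Inflammatory cytokines and NF-kB targets, which lay outside the central 95% on opposite sides, had medians that differed by -0.76. With the mean of the 3 controls as control, the KRAS median was inside the central 95%.

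Clusters without a single gene symbol entered no comparison. Of these, 65 were 2-fold above all 3 control arrays in KRAS-G12C, 56 in PTPN11-G503A and 10 in the Hoxa11 array. In the PTPN11 comparison 496 such clusters were at least 2-fold lower and 170 higher.

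Small RNAs were highest in the PTPN11 arrays: the median deviation of 664 snRNA genes from their own mean was 0.71 in PTPN11-G503A, 0.17 in wild-type PTPN11, 0.12 in the Hoxa11 array and -0.43 in wild-type KRAS. The studied mutations are argued against as the whole source, since 275 small RNA genes were 2-fold apart between the wild-type KRAS and wild-type PTPN11 arrays. Differences in RNA preparation or labelling may contribute: 92.6% of histone genes, whose transcripts lack a poly(A) tail, were higher in both PTPN11 arrays than in the 4 others, against 47.1% of snRNA genes, 25.5% of snoRNA genes, 15.9% of protein-coding genes and 6.67% by chance. An effect of carrying PTPN11 cannot be told apart from this, since the wild-type PTPN11 array lay 0.39 above the median of the 4 other arrays for snRNA and both PTPN11 arrays form 1 pair. The wild-type PTPN11 array lay little above the Hoxa11 array, however, with a median small RNA difference of 0.0456. The Ptpn11 signal was lowest in the PTPN11 arrays. Whether its probes cover an introduced copy is not given, so that signal decides nothing here. The further small RNA difference of 0.29 between wild-type PTPN11 and PTPN11-G503A stays open.

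In the Hoxa11 comparison the control array stood apart: it lay farther from the 4 other arrays for 174 of the 222 genes, and it was 2-fold beyond all 5 others for 82 genes, against 6 for the Hoxa11 array. These values describe the pattern and do not say what set the control apart. A swap of the 2 labels cannot be told apart from correct labels, because the Hoxa11 cluster, 0.58 higher in the array labelled Hoxa11, was near background in both. That rise runs the way the labels say and exceeds those of 99.3% of 6678 genes of like brightness. The rank is not particular to this pair, however. The cluster's rise exceeded those of 99.9% of like genes in the KRAS pair and 98.4% in the PTPN11 pair. Its signal of 4.37 is also close to the filter of 4.09, and PTPN11-G503A had 4.44. An effect of Hoxa11 and divergence of the control line were not tested, for lack of replicates.

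The stefin genes were high in PTPN11-G503A alone. Contaminating neutrophils, which express them, are argued against by the median of -0.24 of the neutrophil list (17 members above the filter in these cells) and by a largest difference of 1.03 among its 22 members, against a median of 6.26 for the 9 stefin genes. Of the genes abundant in neutrophils, Camp (named after its value was seen) was at a log2 signal of 3.98 and S100a9 at 4.75 in PTPN11-G503A, while S100a8 was at 7.33, 0.85 higher than with wild-type PTPN11. Gain of the chromosome region is argued against by the median of -0.11 (SD 0.26) of the 7 nearest other genes above the filter. Signal shared between near-identical copies stays open for single members, since the smallest difference among 9 stefin genes, that of Cstdc3 (named after its value was seen), was 1.07. An effect of PTPN11-G503A and a property of this clone cannot be told apart with 1 array per group, and that common rise of at least 1.07 decides nothing between them.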

How the results depend on the processing

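Protein-coding genes only and 2-fold beyond all 3 control arrays were chosen after seeing the data. No paired analysis was possible because each group holds 1 array, other than through the locus term of the limma fit, which sets each mutant against its own wild type. Each alternative was run for the results it was fixed for and not for all results. Median centring and loess were run only for the 3 counts of a line against its control. The filter at the 75th percentile was not run for control lines, lists or named genes. After quantile normalization 1 list median fell under 5 members. Dim signals limit the values: genes near background have compressed differences.

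Median centring, quantile normalization, loess, no filter and the mean of all clusters kept the 3 counts of genes 2-fold apart within 1.5 times. The filter at the 75th percentile, which tests fewer genes, gave 106 for KRAS, 249 for PTPN11 and 99 for Hoxa11. A 1.5-fold threshold gave 597, 1866 and 751, and a 3-fold threshold 74, 137 and 98. Against the mean of the 3 controls the count was 686 for PTPN11 and 114 for Hoxa11; the cause was not tested. Only 49, 193 and 18 genes were 2-fold beyond all 3 controls. With protein-coding genes only, PTPN11 had 289.

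The shared mutant effect was the least stable: 12 genes became 1 with quantile normalization, 0 without the filter, 0 without the locus term and 4 with protein-coding genes only, while the other settings gave 11 or 12. Of the 11 genes with the 75th percentile filter, 8 were among the 12. All 12 genes code for protein, so none left the count for its class. The cause was otherwise not tested, except that the locus term removes the difference between both pairs. At an unadjusted p of 0.05 limma called 1249 genes as reported, 2003 without the filter and 414 without the locus term. The 51 genes moved the same way in both mutants became 28 with the 75th percentile filter, 189 at 1.5-fold and 18 at 3-fold.

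The KRAS and PTPN11 correlation stayed between 0.18 and 0.26. The KRAS and Hoxa11 correlation was -0.0029 with the 75th percentile filter and -0.0008 as Spearman's rho, and the PTPN11 and Hoxa11 correlation 0.037 and 0.18; the cause was not tested.

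Between control lines, 1.5-fold gave 2049, 1527 and 1695 genes for wild-type KRAS and PTPN11, wild-type KRAS and no Hoxa11, and wild-type PTPN11 and no Hoxa11. A 3-fold threshold gave 242, 154 and 186. With protein-coding genes only the first pair had 295 and the second 336.

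Named genes were run with quantile normalization, the mean of all clusters and the mean of the 3 controls, and lists also without the filter. Among these, values past 2-fold or outside the central 95% changed sign only against the mean of the 3 controls. Apart from the control levels given above, the cause was not tested. Smaller values changed sign elsewhere too, such as the lysosome median in PTPN11 after quantile normalization. Medians became 0.0547 for monocyte markers and 0.0096 for cholesterol synthesis in KRAS, 0.42 for immediate early genes and 0.0708 for glycolysis in PTPN11, and 0.0614 for glycolysis in the mean of both mutants. That of immediate early genes then lay above the central 95%, at the 99.99 percentile. In KRAS, Dock1 became -0.52, Bcl2a1a 0.20, Lilrb4a 0.28, Lilr4b 0.19 and Map1b -0.19. In PTPN11, Hpgd became -1.38 and Bnip3 0.0601. In Hoxa11, Far2 became -0.44, Cd24a 1.44, Hpgd 1.79, Bcl2a1a -0.13, Lilrb4a -0.14 and Lilr4b -0.0817. There, 45 values of named genes lost and 42 gained 2-fold, of 597, and 16 of 124 list medians left and 26 entered the range outside the central 95%. With quantile normalization 2 lost and 1 gained it, and with the mean of all clusters 2 lost it. Of the list medians, 3 left and 2 entered the range outside the central 95% with quantile normalization, and 6 left and 6 entered it without the filter.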

Other observations

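All tests in this part were chosen after the results were seen.

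Some list members stood apart in PTPN11-G503A alone. The platelet chemokine gene Ppbp was at log2 5.93 in PTPN11-G503A and at most 3.54 in the other arrays, and the interleukin-7 receptor gene Il7r at 5.37 against at most 3.71. The MLL fusion target Pbx3 was 7.76 there and at most 6.05 elsewhere. Ppbp did not stand for its list: the other megakaryocyte markers above the filter, Itgb3 and Gp9, were at -0.44 and -0.26 in the same comparison. Cycs, which encodes cytochrome c, was 0.96 higher with PTPN11-G503A, while oxidative phosphorylation genes had medians of 0.00, 0.08 and -0.04 in the KRAS, PTPN11 and Hoxa11 comparisons, all inside the central 95%. MYC and nucleolar genes (0.02, 0.22 and -0.05) and cytosolic ribosomal protein genes (-0.01, 0.09 and -0.03) were inside it too.

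A hypothesis is that part of the genes called in a comparison vary between these lines whatever the studied change. If so, they should be apart between control arrays that the comparison does not use. Of genes called in the KRAS comparison, 36.8% were 2-fold apart between wild-type PTPN11 and the line without Hoxa11, against 3.39% of all genes tested. For PTPN11 the share between the other controls was 22.8% against 3.20%, and for Hoxa11 24.3% against 4.56%. With protein-coding genes only the shares were 35.6%, 30.4% and 26.1%. A part of the called genes thus also differed between control lines. The excess over all genes does not decide the hypothesis, since that reference was not matched on signal or variability. Nor does it exclude an effect of the studied change on the same genes.

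Another hypothesis is that the agreement of both mutants is no more than agreement by chance. With a gap of at least 2-fold between all arrays of either side, 31 genes parted the mutant from the wild-type arrays, and 8 parted KRAS-G12C and wild-type PTPN11 from the others. The 4 arrays allow only 3 such partings, too few for a share under 0.05. Parting KRAS from PTPN11 arrays gave 336 genes, of which 223 were small RNAs. For these, differences between the arrays and an effect of carrying PTPN11 cannot be told apart. limma called 12 genes for the mutants and 0 for the crossed parting, where 263 passed an unadjusted p of 0.05. Each of these fits takes the effect of the other as its error, so this contrast is no separate check against chance agreement.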
